A study of Mus musculus with 6 samples.

How the data were processed

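ATAC-seq libraries were made from about 5000 sorted HSCs each, 3 from mice given DMSO and 3 from mice given tunicamycin, as the labels' treatment field states. One peak list per library was used, so peaks had been called by library and not on pooled samples. The submitters' processing notes name Trim Galore 0.4.4, Bowtie2 2.2.9, Picard, MACS2 and featureCounts and the mouse build mm10, without the role or settings of each. How reads were filtered, whether read ends were shifted for the transposase, and the calling threshold are not given in the sources used here. Each list holds for every peak its position and summit, a display score, a fold enrichment (a ratio over background), a −log10 p-value and a −log10 q-value, all as the authors deposited them. The smallest deposited −log10 q in each list corresponded to a q-value of 0.0482 to 0.04999. Fold enrichments as deposited ran from 1.48 to 31.1. These values belong to each peak and were used only to describe, rank or filter peaks within a list. Read depth per library is unknown from peak lists, so the number of peaks, 28501 to 62478, serves here as a guide to how sensitive a library was, beside the percent of regions called in at least 2 libraries that it called, 45.1 to 90.5.

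Peaks on chromosomes 1 to 19, X and Y were kept, and 109 to 138 peaks per library on other sequences were left out. No list held an interval in duplicate. Peaks of all libraries were merged where they overlapped by at least 1 bp into union regions, and a library called a region if any of its peaks lay in it. A region open in 3 of 3 libraries of a group and 0 of 3 of the other was termed tunicamycin-only or DMSO-only. For regions called in exactly 3 libraries, counts of the 20 possible sets of 3 libraries were fitted by a Poisson log-linear model with 1 effect per library, and observed counts were divided by the expectation with exact Poisson 95% intervals. Similarity of libraries was the base-pair Jaccard index. Measures per library were compared by two-sided exact permutation tests (smallest p 0.10), shares by exact binomial 95% intervals, and gene lists by two-sided Fisher's exact tests against the other regions called in exactly 3 libraries, with Benjamini-Hochberg adjustment.

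Regions were assigned to the nearest of 21887 protein-coding genes of a RefSeq gene table for GRCm38.p6, the assembly that mm10 denotes, within 100 kb. The planned assignment used transcription start sites. The table used here gives no strand, so the nearest gene body was taken, with regions inside several genes given to the gene with the nearer end, and the share of peaks near a promoter became the share within 1 kb of either gene end. Exons and introns were not distinguished. The planned test of 32 transcription factor motifs needs genome sequence and was not run. The 20 gene lists covered the ER stress response, integrated stress response, EMP and PMP22 family, HSC identity, cell cycle, apoptosis and p53 targets, AP-1 and immediate early, NF-kB and inflammation, interferon response, oxidative stress, autophagy and lysosome, markers of megakaryocytes, erythroid cells, neutrophils and monocytes, macrophages, lymphoid cells and stroma or endothelium, chromatin regulators, mitochondria and glycolysis, and housekeeping controls. Of 542 entries 539 matched a protein-coding gene, Mx1, Mx2 and Ng2 being the exceptions, and 18 genes stood in more than 1 list. Separately, a list gene counted as accessible in all libraries if a region within the gene or 1 kb of it was called in all 6.

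The groups, main tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The tests of the position of separated regions and the permutation test at Emp1 were not part of that plan. Other later additions are named where they are reported. Under the naming rule Emp1 was named, then every stress-response gene next to a separated region, and up to 4 such genes of each other list. The genes nearest to the 10 tunicamycin-only and 10 DMSO-only regions of highest rank were named last. Rank was the lowest, over the 3 calling libraries, of the region's percentile by fold. Genes in the account of regions open in all libraries, and those with several tunicamycin-only regions, were chosen as examples after their values were seen. Alternatives were peaks with a q-value of at most 1e-05, lists limited to the 28501 peaks with the highest −log10 q, autosomes only, calls that require 50% cover of a region, windows of 250 bp to each side of the summits, other backgrounds and distances, the same-numbered libraries as pairs, and each library left out in turn. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and merging with bedtools 2.31.1 gave the same 82993 regions. The model and list tests were tested on simulated data. In 20 simulations of 82993 regions without a treatment effect, the ratio of observed to expected tunicamycin-only regions ran from 0.896 to 1.08. With 200 planted regions it ran from 1.13 to 1.28. The simulated calls were independent and followed the model itself, so these ranges hold only where the model does. In the data, sets of 3 libraries that mixed the groups had ratios of 0.639 to 4.81, so the simulated range is no measure of chance there. Random lists gave an unadjusted p under 0.05 in 4.25% of 400 tests, and a list planted at 5% against 1% did in 20 of 20 simulations. The real lists were nearest to only 0 to 0.478% of the regions they were compared with. The simulation therefore does not show that a difference of a real list would be found.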

Results

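Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in haematopoietic stem cells (HSCs) of mouse bone marrow. The cells carried the surface phenotype CD48-negative, CD150-positive, lineage-negative, Sca-1-positive and c-Kit-positive, and about 5000 cells went into each library. Wild-type C57BL/6J mice had received an intraperitoneal injection of tunicamycin at 2 mg per kg (3 libraries) or of DMSO, the solvent (3 libraries). Tunicamycin blocks N-linked glycosylation and so burdens the endoplasmic reticulum (ER) with misfolded protein. Each library was represented by its own list of accessible peaks, and the comparison asked which regions of HSC chromatin were called open after ER stress and not without it, or the reverse. Read depth is unknown from such lists, so a missing call does not show closed chromatin. A call in both groups likewise does not show equal accessibility, because calls record presence and not degree. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

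Genes of the ER stress response were accessible in HSCs with and without tunicamycin. Of 40 such genes, 39 carried, inside the gene or within 1 kb of it, a region called in all 6 libraries. They included Hspa5, the ER chaperone BiP, Xbp1, a transcription factor of the unfolded protein response, and Dnajb9, an ER co-chaperone, and the exception was Mbtps2, a protease that activates ATF6. Among 30 genes of the integrated stress response the number was 26, with Atf4, Ddit3 (CHOP), Trib3, Asns and Chac1 among them and Nupr1, Shmt2, Stc2 and Vldlr outside. HSC identity genes held such a region in 31 of 40 cases, Hlf and Mecom included, and all 20 housekeeping genes did. So did 35 of 36 cell cycle genes and 27 of 28 chromatin regulators, so a high share was not particular to stress genes. Among marker genes of other cell types the number was 10 of 28 for neutrophils and monocytes, where Elane and Mpo lacked a region shared by all 6 libraries, 11 of 22 for erythroid cells, 11 of 20 for megakaryocytes, 8 of 18 for macrophages, 15 of 29 for lymphoid cells and 8 of 21 for stroma and endothelium.

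The extent of accessible chromatin differed more between the DMSO libraries than between the groups. On chromosomes 1 to 19, X and Y, the DMSO libraries held 62478, 38217 and 28501 peaks for replicates 1, 2 and 3, and the tunicamycin libraries held 44952, 56865 and 47789. The means were 49868.7 ± 6222.8 peaks (SD, n = 3) after tunicamycin and 43065.3 ± 17499.7 (SD, n = 3) after DMSO, and a two-sided exact permutation test of the difference of 6803 gave p = 0.50. Peaks covered 22.6 ± 2.88 Mb (SD, n = 3) after tunicamycin and 19.2 ± 8.74 Mb (SD, n = 3) after DMSO, with an exact p of 0.50. Peaks within 1 kb of either end of a protein-coding gene made up 26.6% ± 2.35 (SD, n = 3) of the tunicamycin lists and 29.8% ± 5.43 (SD, n = 3) of the DMSO lists, again with an exact p of 0.50. With 3 libraries against 3 the smallest p such a test allows is 0.10, and Benjamini-Hochberg adjustment over 6 measures of this kind raised every p to 1. Without DMSO replicate 1, the longest list, the differences were 16510 peaks, 8.26 Mb and −6.09 percentage points near gene ends (exact p = 0.10 each, the smallest possible), and without DMSO replicate 3, the shortest list, they were −479 peaks, −0.237 Mb and −0.732 percentage points (exact p = 1 each). With lists limited to one length the share near gene ends differed by 0.0269 percentage points.

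**Figure D1:**
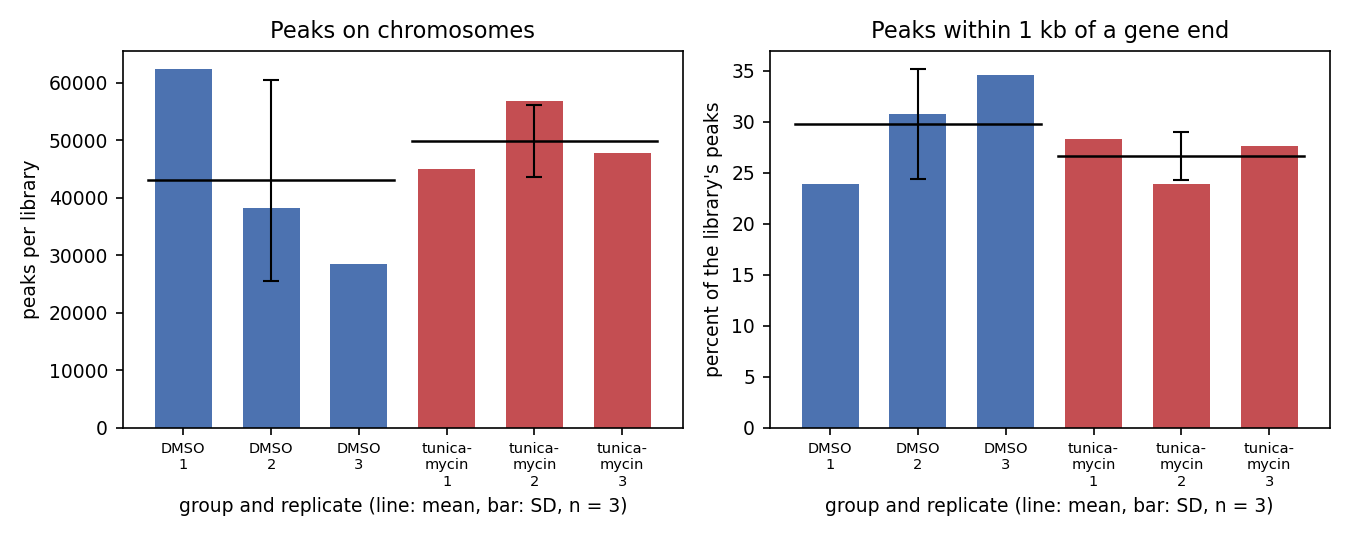
Left, peaks on chromosomes 1 to 19, X and Y in each library; right, percent of those peaks within 1 kb of an end of a protein-coding gene. Bars are libraries (blue, DMSO; red, tunicamycin), and black lines and error bars are group means and SD (n = 3). The DMSO libraries span 28501 to 62478 peaks and enclose all 3 tunicamycin libraries.

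Most reproducible open regions were shared by both groups. Merging all peaks gave 82993 regions, of which 20810 (25.1%) were called in all 6 libraries and 26871 in 1 library. Of the 36185 regions present in at least 2 of 3 DMSO libraries, 90.6% were also present in at least 2 of 3 tunicamycin libraries. In the other direction 72.9% of 44961 regions were shared. The base-pair Jaccard index, the overlap of 2 peak sets divided by their union, averaged 0.507 for library pairs of one group and 0.502 for pairs from different groups. The difference of 0.00454 had a one-sided exact p of 0.40 over the 10 splits of 6 libraries, where the smallest possible p is 0.10. Tunicamycin libraries resembled each other at 0.565 to 0.593, DMSO libraries at 0.339 to 0.482, and pairs across groups at 0.372 to 0.581. Without DMSO replicate 1 the difference was 0.0841 (exact p = 0.10, the smallest possible), and without DMSO replicate 2 it was 0.0328 (exact p = 0.30). It turned negative when tunicamycin replicate 1 (−0.0261), 2 (−0.0376) or 3 (−0.0325) was left out.

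A small set of regions separated the groups fully. Between them, 567 regions (0.683% of all) were open in 3 of 3 tunicamycin and 0 of 3 DMSO libraries, near genes such as Slc7a5, Ddit4, Ccnd1 and Lifr, and 81 regions (0.0976%) showed the opposite pattern, near genes such as Gbp6, Mybl2 and Cth. With peaks of q at most 1e-05, 268 of the 567 and 11 of the 81 stayed separated, and with lists of one length 24 and 2 did. Another 3640 regions were open in all 3 tunicamycin libraries and in DMSO replicate 1, the longest DMSO list, but in neither other DMSO library. Of the tunicamycin-only regions 61.0% (346 of 567, exact 95% interval 56.9 to 65.1) lay inside a protein-coding gene, against 54.9% of the 7360 other regions called in exactly 3 libraries (Fisher's exact test, two-sided p = 0.00499, adjusted p = 0.01996 over 4 tests of position). Only 9.0% of them (51 of 567, interval 6.77 to 11.7) lay within 1 kb of a gene end, where the other such regions reached 10.8% (Fisher's exact p = 0.203, adjusted p = 0.262) and regions open in all 6 libraries 40.7%. Of the DMSO-only regions 39 of 81 were inside a gene (48.1%, interval 36.9 to 59.5, Fisher's exact p = 0.262) and 5 near a gene end (6.17%, interval 2.03 to 13.8, p = 0.210), each with an adjusted p of 0.262. The tests of position were not part of the plan. They and the intervals treat regions as independent and cover counting error only.

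The number of separated regions was then set against the number that each library's own rate of calls would give. That rate was fitted to the same counts, so it also takes up a difference shared by a whole group. A log-linear model with 1 effect per library expected 519 tunicamycin-only regions, so that the observed number was 1.09 times the expectation (95% Poisson interval 1.01 to 1.19), rank 6 of the 20 possible sets of 3 libraries. For the DMSO-only regions it expected 40.6, a ratio of 1.99 (interval 1.58 to 2.48) and rank 4. Sets that mixed the groups stood higher, with ratios of 4.81, 2.90 and 2.49 for DMSO replicates 2 and 3 with tunicamycin replicates 1, 2 and 3. DMSO replicates 2 and 3 also shared more regions as a pair than the model expected (ratio 6.10). The DMSO-only set holds that pair too, so its ratio of 1.99 cannot be read as an excess of the whole group. No single region could be called different, since presence in 3 against 3 libraries cannot reach a p below 0.10. Leaving out 1 library eased the criterion in its group to 2 calls of 2, or to absence from 2. This raises the counts, so they cannot be set beside those of all 6 libraries. Omissions within 1 group ease it alike, so their counts can be compared with each other. Tunicamycin-only regions then numbered 4230 without DMSO replicate 1, the highest count of any omission, and 1806, 906 and 1237 without tunicamycin replicates 1, 2 and 3. With all 6 libraries, 3640 regions were called in all 3 tunicamycin libraries and in DMSO replicate 1 only, so the number of tunicamycin-only regions depended on that library. DMSO-only regions numbered 411, 279 and 750 without DMSO replicates 1, 2 and 3 and 131, 205 and 125 without tunicamycin replicates 1, 2 and 3. The ratio of 1.09 fell below 1 without DMSO replicate 2 (0.947) and without tunicamycin replicate 2 (0.972) or 3 (0.959), and that of 1.99 became 3.82, 0.70 and 1.04 without DMSO replicates 1, 2 and 3.

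**Figure D2:**
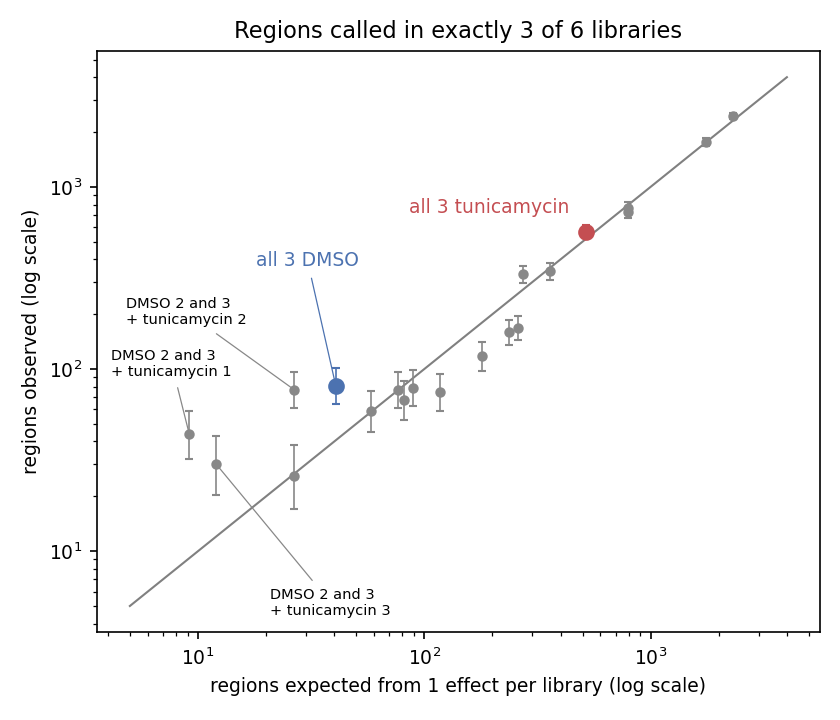
Number of regions called in exactly 3 of 6 libraries (vertical, log scale) against the number expected from 1 effect per library (horizontal, log scale), 1 point per set of 3 libraries, with 95% Poisson intervals and the line of equality. The 3 tunicamycin libraries (red, 567 regions) lie close to the line, and the 3 sets that combine DMSO replicates 2 and 3 with a tunicamycin library lie above it.

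None of the 40 ER stress genes lay next to a group-separated region in either direction. These genes were nearest to 0 of 536 tunicamycin-only regions and to 12 of 6897 other regions called in exactly 3 libraries (0.174%, Fisher's exact test, two-sided p = 1). With so low a background a smaller share could not be seen, whereas a large excess could have been and was absent. In the integrated stress response 2 of 30 genes did, both tunicamycin-only. Slc7a5, which encodes a transporter of large neutral amino acids, had one 3.90 kb outside the gene (mm10, chromosome 8, 121911413 to 121911755), where the authors' fold enrichment was 4.11 to 4.49 in the 3 tunicamycin libraries. Ddit4, which encodes an inhibitor of mTORC1 signalling, had one 12.03 kb outside the gene (chromosome 10, 59963666 to 59963930), with fold enrichments of 3.94 to 4.55. Integrated stress response genes were nearest to 2 of 536 tunicamycin-only regions within 100 kb of a gene (0.373%) and to 9 of 6897 other regions called in exactly 3 libraries (0.130%, Fisher's exact test, two-sided p = 0.186, adjusted p = 1). The Slc7a5 region stayed separated with peaks of q at most 1e-05 and with lists of one length, and the Ddit4 region did in neither.

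The lists for HSC identity, cell cycle, apoptosis and p53 targets, and chromatin regulators held 9 genes next to a tunicamycin-only region and none next to a DMSO-only region. In the HSC list, 2 of 40 genes had one: Fli1, an ETS-family transcription factor, 27.4 kb outside the gene (chromosome 9, 32570677 to 32570977), and Etv6, an ETS-family repressor, inside the gene (chromosome 6, 134141348 to 134141647). In the cell cycle list these were Ccne1 (cyclin E1), at 3.46 kb (chromosome 7, 38094369 to 38094674), and Ccnd1 (cyclin D1), at 42.0 kb (chromosome 7, 144981670 to 144982016). Among apoptosis and p53 targets they were Pmaip1 (NOXA), at 10.7 kb (chromosome 18, 66447642 to 66448095), and Bcl2l11 (BIM), inside the gene (chromosome 2, 128156054 to 128156465), both of which encode BH3-only proteins that promote cell death. Chromatin regulators contributed 3 of 28 genes, each with the region inside the gene: Smarca4, the BRG1 remodelling ATPase (chromosome 9, 21698727 to 21699219), Dnmt3a, a DNA methyltransferase (chromosome 12, 3861720 to 3862152), and Chd4, a remodelling ATPase of the NuRD complex (chromosome 6, 125129713 to 125130226). None of these lists stood apart from its share among 6897 other regions called in exactly 3 libraries: HSC identity was nearest to 2 of 536 tunicamycin-only regions (0.373%) against 0.478% (Fisher's exact p = 1), cell cycle to 2 against 0.174% (exact p = 0.268), and apoptosis and p53 targets to 2 against 0.203% (exact p = 0.323). None of the 9 regions stayed separated with lists of one length, and with peaks of q at most 1e-05 only those at Fli1, Ccne1, Bcl2l11 and Smarca4 did.

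The remaining lists held few separated regions. Irf8, an interferon-regulated factor of the monocyte lineage that belonged to both the interferon and the neutrophil and monocyte lists, had a tunicamycin-only region 65.0 kb away (chromosome 8, 120821439 to 120821876). Gbp6, an interferon-induced GTPase, had the only DMSO-only region of any list, 9.40 kb away (chromosome 5, 105260843 to 105261768). Tunicamycin-only regions also lay nearest to Sod1, a superoxide dismutase (chromosome 16, 90199161 to 90199603), Tfe3, a regulator of lysosomal genes (X, 7776449 to 7777029), the lymphoid factors Eomes (chromosome 9, 118416386 to 118416775) and Pax5 (chromosome 4, 44564615 to 44565060), and the adipocyte hormone gene Adipoq (chromosome 16, 23165447 to 23165796). Of the regions at these 7 genes none stayed separated with lists of one length, and those at Tfe3, Eomes and Adipoq did with peaks of q at most 1e-05. None of the AP-1, NF-kB, megakaryocyte, erythroid, macrophage, mitochondria and glycolysis, housekeeping or EMP and PMP22 family genes had one. Over 20 lists and both directions, 40 Fisher's exact tests gave 0 lists with an adjusted p under 0.05 and 0 with an unadjusted p under 0.05. With only 0 to 3 separated regions per list and direction, a difference could go unseen. The smallest unadjusted values were 0.130 for interferon genes among DMSO-only regions (1 of 69), 0.136 for chromatin regulators among tunicamycin-only regions (3 of 536, 0.560%, against 15 of 6897, 0.217%) and the 0.186 of the integrated stress response.

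None of the 10 tunicamycin-only regions that ranked highest by fold enrichment had a stress-list gene as its nearest gene. The ER stress and integrated stress response lists were nearest to only 0.174% and 0.130% of the other regions called in exactly 3 libraries. Their absence among 10 regions was therefore nearly certain in advance and is no result about stress genes. The first of the 10 regions was 391 kb from Zfp462 (chromosome 4, 54552952 to 54553794), with fold enrichments of 6.93 to 7.76. It was followed by regions near Acvr2a, an activin receptor (119 kb away, chromosome 2, 48694425 to 48694929), Arap2 (12.7 kb, chromosome 5, 62778673 to 62779174) and Lifr, the leukaemia inhibitory factor receptor (10.6 kb, chromosome 15, 7079850 to 7080207). The next were within Opalin (chromosome 19, 41071545 to 41072077), Atp2c1 (chromosome 9, 105502417 to 105502737) and Ccdc88a (chromosome 11, 29428838 to 29429230), 102 kb from Prlr, the prolactin receptor (chromosome 15, 10074984 to 10075675), and within Klhdc10 (chromosome 6, 30449164 to 30449747) and Ep400, a chromatin remodeller (chromosome 5, 110703860 to 110704585). The 10 highest DMSO-only regions lay inside Fhit, Foxj2, Mybl2 and Smim31 and outside Zbtb8os, Olfm2, Btg3, C330007P06Rik, Rps29 (387 kb away) and Cth. The first of them, 0.973 kb from Zbtb8os (chromosome 4, 129350692 to 129350996), had fold enrichments of 5.75 to 7.47, and that at Mybl2, a cell cycle transcription factor, lay at chromosome 2, 163082707 to 163083041. The lowest percentile by fold over the 3 calling libraries had a median of 15.8 for tunicamycin-only regions, 9.10 for DMSO-only regions and 17.4 for the other regions called in exactly 3 libraries. Of the 20 regions named by this rank, 18 stayed separated with peaks of q at most 1e-05 and 9 with lists of one length, against 8 and 1, that of Slc7a5, of the 18 regions named through gene lists. Because the rank selects strong peaks and the lists do not, this contrast follows in part from how the regions were chosen.

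Accessibility around gene groups was compared further as the percent of a list's regions that each library called, minus the same percent over all regions called in at least 2 libraries. Neutrophil and monocyte genes stood at 2.15 ± 1.05 percentage points (SD, n = 3) after tunicamycin and −5.15 ± 3.97 (SD, n = 3) after DMSO, with all 3 tunicamycin libraries above all DMSO libraries (difference 7.30, exact permutation p = 0.10). A peak lay at 21, 16 and 11 of the 28 genes of this list in DMSO replicates 1, 2 and 3 and at 17, 21 and 19 in the tunicamycin replicates. Oxidative stress genes, which include Nfe2l2 and Hmox1, stood at 6.47 ± 2.63 and 2.83 ± 1.28 (SD, n = 3 each, difference 3.65, exact p = 0.10). Megakaryocyte genes were the third list without overlap, at −2.04 ± 0.329 after tunicamycin and 1.09 ± 3.36 after DMSO (SD, n = 3 each, difference −3.12, exact p = 0.10). Chance gives 10% of lists, or 2 of 20, without overlap, and the smallest adjusted p over the 20 lists was 0.667. The neutrophil and monocyte groups overlapped without tunicamycin replicate 2 (difference 4.77), the oxidative stress groups without tunicamycin replicate 1 (1.33), DMSO replicate 1 (2.57) or DMSO replicate 3 (3.14), and the megakaryocyte groups without DMSO replicate 1 (−4.13) or 2 (−3.18) or tunicamycin replicate 1 (−3.82) or 3 (−4.17). The ER stress list stood at 3.53 ± 1.91 after tunicamycin and 4.42 ± 2.13 after DMSO (SD, n = 3 each, difference −0.899, exact p = 0.50), and the integrated stress response at 3.597 ± 3.31 and 4.27 ± 0.498 (SD, n = 3 each, difference −0.674, exact p = 0.70). Over the alternatives the ER stress difference ran from −2.55 without DMSO replicate 1 to 2.99 with 50% cover, without overlap of the groups in both, and was 2.09 with lists of one length, with overlap. That of the integrated stress response ran from −2.02 with peaks of q at most 1e-05 to 2.47 with 50% cover, with overlap in both.

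In the other 15 lists the libraries of the groups overlapped. Differences above 0 were 5.43 percentage points for macrophage genes, 4.72 for chromatin regulators, 4.12 for autophagy and lysosome, 0.869 for interferon response, 0.782 for lymphoid, 0.649 for cell cycle and 0.468 for NF-kB and inflammation. Differences below 0 were −0.0569 for mitochondria and glycolysis, −0.225 for stroma and endothelium, −1.35 for apoptosis and p53 targets, −2.28 for HSC identity, −2.35 for erythroid, −3.003 for AP-1 and immediate early, −3.50 for the EMP and PMP22 family and −7.66 for housekeeping genes. Two-sided exact permutation p-values for these 15 lists ran from 0.20 to 1. With each library left out in turn, the direction held throughout for 5 of them, macrophage, chromatin regulator, HSC identity, AP-1 and housekeeping genes, the last at −1.27 without DMSO replicate 2, and turned at least once for the other 10. Among these, autophagy and lysosome fell to −0.239 without tunicamycin replicate 3, stroma and endothelium stood at 8.49 without DMSO replicate 1, and the EMP and PMP22 family at 4.01 without tunicamycin replicate 2. With peaks of q at most 1e-05, 0 of 20 lists were without overlap. With lists of one length the neutrophil and monocyte, oxidative stress and megakaryocyte differences became −0.275, 0.147 and 6.51, each with overlap. The EMP and PMP22 family (−37.6, on only 9 regions), erythroid (−10.3, 28 regions) and housekeeping genes (5.46, 41 regions) were then without overlap. By chance 2 of 20 lists would be without overlap.

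**Figure D3:**
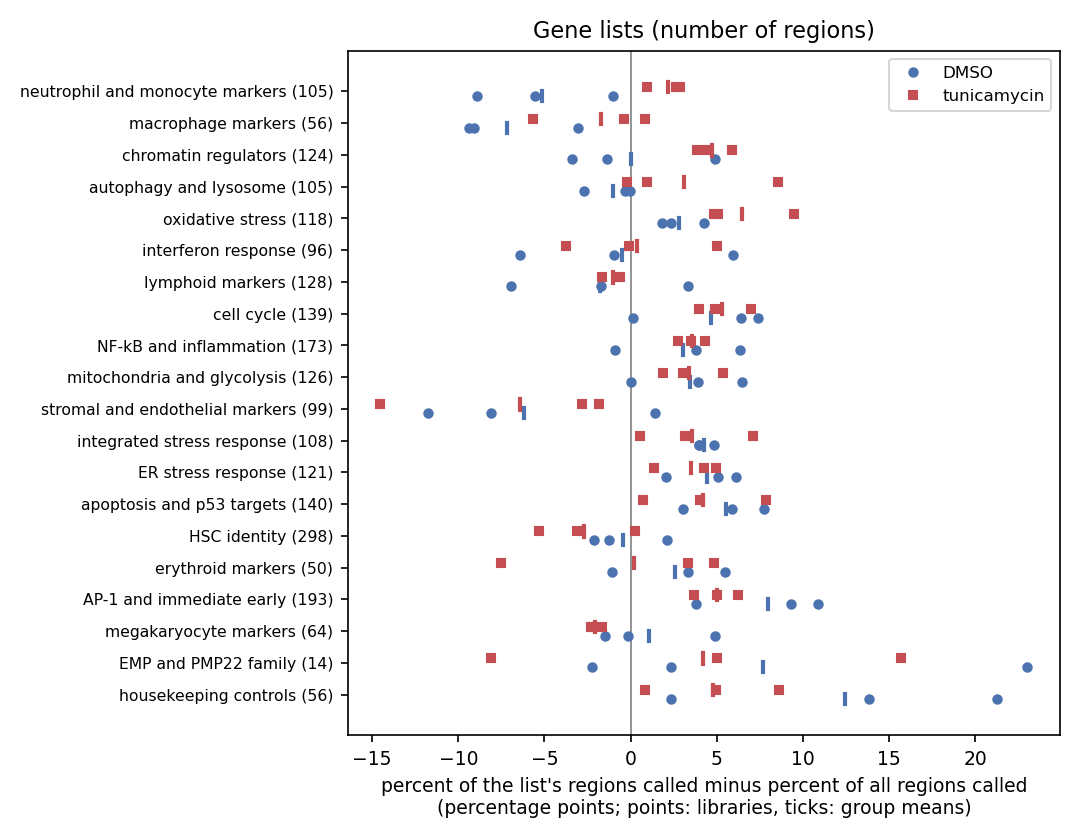
For 20 gene lists (number of regions in brackets), the percent of the list's regions called in a library minus the same percent over all regions, in percentage points. Both percents are over regions called in at least 2 libraries. Circles are DMSO and squares tunicamycin libraries, and ticks mark group means (n = 3). Groups are without overlap for neutrophil and monocyte, oxidative stress and megakaryocyte genes, and overlap for the ER stress response.

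Emp1, the epithelial membrane protein gene that the series title names, was accessible in HSCs under both treatments. Of 17 regions nearest to it, 3 were called in all 6 libraries. The first lay inside the gene (mm10, chromosome 6, 135364168 to 135364785), 1.93 kb from the nearer gene end, with fold enrichments of 5.17 to 10.7, the second also inside the gene (135377494 to 135378081), and the third 67.6 kb away (135450442 to 135451020). None of the 17 separated the groups, and the region closest to doing so, 61.7 kb away (135444612 to 135445218), was open in 3 of 3 tunicamycin and 1 of 3 DMSO libraries. The region nearest to a gene end (135362605 to 135363058, 0.282 kb from it) was called in 2 tunicamycin and 3 DMSO libraries. Its difference in calls was −66.7 percent of libraries both with peaks of q at most 1e-05 and with lists of one length. For the region 61.7 kb away these differences were 66.7 and 33.3. The libraries called 8.0 ± 1.0 Emp1 regions after tunicamycin and 8.67 ± 2.52 after DMSO (SD, n = 3 each), with an exact permutation p of 0.90. In the same family Emp2 and Emp3 carried a region called in all 6 libraries, and Pmp22 did not. The Emp1 difference of −0.667 regions turned to 0.5 without DMSO replicate 1 (exact p = 0.80), and with lists of one length it was −2.67 with an exact p of 0.10, the smallest possible.

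**Figure D4:**
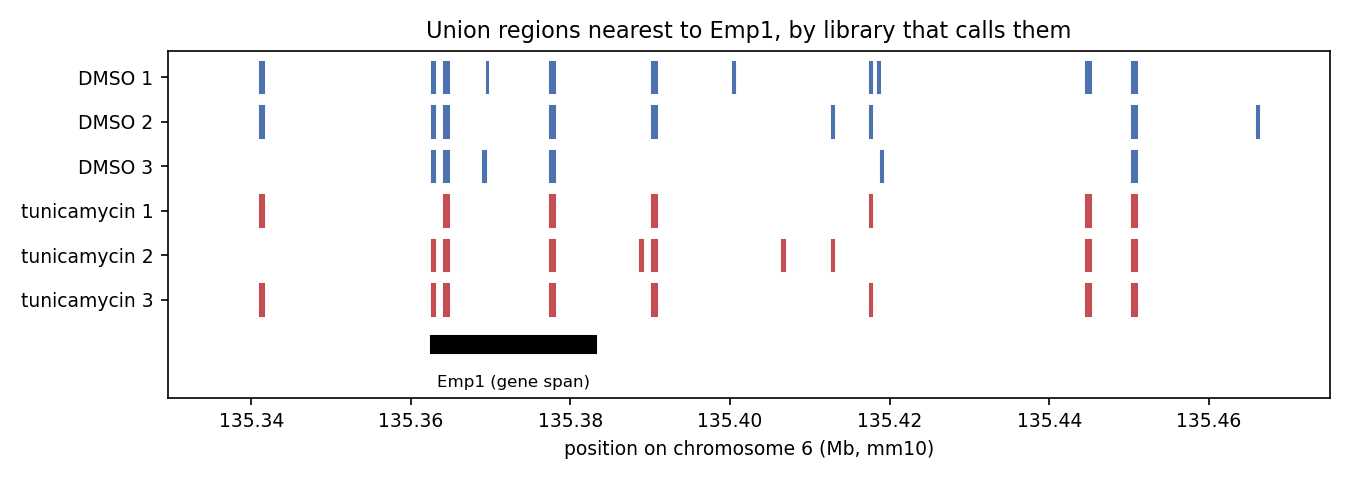
Regions nearest to Emp1 on chromosome 6 (horizontal, Mb, mm10), drawn to scale in each library that called them (blue, DMSO; red, tunicamycin), with the gene span in black. The 3 regions called in all 6 libraries appear as full columns, and no region is present in all tunicamycin libraries and absent from all DMSO libraries.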

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

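Tests chosen only after the result was seen were the omission of DMSO replicates 2 and 3 together and the assignment to the nearest gene end. No gene list next to separated regions passed the adjusted threshold under any alternative, and of the values that answer a comparison 91 kept their direction within the spread or 1.5 times, 24 moved further and 11 turned direction. For single named regions these numbers were 475, 128 and 2. The labels share replicate numbers, but same-numbered libraries did not deviate together (correlations −0.0166, −0.0166 and −0.0083), and the paired replicate block, which cannot move the differences of 6803 peaks, 3.43 Mb and −3.16 percentage points between groups of equal size, gave an exact sign-flip p of 0.50 for each (smallest possible 0.25), and 5 of 20 lists went one way in all 3 pairs, the number that chance gives (25%). Peaks of q at most 1e-05 gave 27 DMSO-only regions, 11 of them among the 81 (ratio to expectation 1.28), and kept 268 of the 567 tunicamycin-only regions. They gave 0 lists without overlap, as did list regions called in at least 3 libraries. Lists of one length gave 354 tunicamycin-only regions, 24 of them among the 567, and 117 DMSO-only regions, 2 of them among the 81, with ratios of 1.297 and 1.15 for tunicamycin-only and DMSO-only regions, a difference of 0.0269 percentage points near gene ends and one of −2.67 Emp1 regions (exact p = 0.10). For the Emp1 region at 135390251, called in 3 tunicamycin and 2 DMSO libraries, the difference in calls turned from 33.3 to −66.7 percent of libraries with lists of one length and to −33.3 with 50% cover. Leaving out each library in turn gave ranges of 663 to 4230 tunicamycin-only and 125 to 750 DMSO-only regions, ratios of 0.947 to 1.15 and 0.70 to 3.82, differences of −479 to 16510 peaks, −0.237 to 8.26 Mb, −6.09 to −0.732 percentage points near gene ends, −0.0376 to 0.0841 in Jaccard index and −2.0 to 0.5 Emp1 regions, and 2 to 6 lists without overlap. Fewer libraries make the criterion easier, which raises the counts of separated regions. They also make groups without overlap more likely by chance, so 2 to 6 lists cannot be set beside the 2 of 20 expected with all 6 libraries. The cause of the other changes was not tested. Without DMSO replicates 2 and 3 together 964 regions were tunicamycin-only. The motif test was not run for want of sequence, distances to start sites were replaced by those to gene ends, and equal lengths leave no difference in peak number by construction. Unknown read depth limits every absence of a call.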

Other observations

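Tests chosen only after the result was seen were the count of genes with several regions, those of list length and library sensitivity, the splits for the number and ratio of separated regions, the share of DMSO regions near gene ends, and the comparison with other sets of libraries in the last paragraph.

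Several genes carried more than 1 tunicamycin-only region. Prex1, a Rac activator, Trio and Spink2 had 3 each, and the other genes of this kind had 2, among them Foxp1, a transcription factor, Ifngr1, a chain of the interferon gamma receptor, Inpp4b, a phosphoinositide phosphatase, Arap2 and Ep400. The total of 29 genes compared with a median of 18 in 10000 random draws of as many regions from those called in exactly 3 libraries (middle 95% of draws 11 to 26), and a share of 0.0066 of draws had as many. The largest number at 1 gene, 3, was reached in a share of 0.546 of draws. Of the tunicamycin-only regions 61.0% lay inside a gene, against 54.9% of the other regions called in exactly 3 libraries. Whether this difference in position adds to the 29 genes was not tested.

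The excess of 567 tunicamycin-only over 81 DMSO-only regions, a ratio of 7.0 (95% interval 5.54 to 8.95), may come from the DMSO libraries and not from the treatment. With lists of one length 75.2% (exact 95% interval 71.0 to 79.0) of separated regions were tunicamycin-only, an imbalance that list length alone would not give. A model with 1 effect per library expected 72.9% there. Only 24 of the 567 regions were among those separated with lists of one length, so for the 567 themselves list length stays open. For the deposited lists that model, which has no treatment term, expected a ratio of 12.8, higher than that observed. Its effects were fitted to the same counts, so they also take up a difference shared by a whole group. Lower sensitivity of single DMSO libraries stays open and could account for the direction, but the model cannot tell it from the treatment. Of the 10 splits of the 6 libraries, 5 gave as many separated regions as the real 648, the highest other being 2498 for the 3 longest lists against the rest, a structure that follows list length, and 2 gave as high a ratio of observed to expected (real 1.159, highest other 1.163). All 10 gave the real number of gene lists past the threshold, which was 0 with a highest other of 0, and 10 splits are too few for a share under 0.05.

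DMSO replicates 2 and 3 shared 329 regions found in no other library, where library sensitivity alone expected 54.0, a ratio of 6.10 (95% interval 5.45 to 6.79) and the highest of 15 pairs. Regulatory regions at gene ends are argued against, since 0.912% of them (3 of 329, exact 95% interval 0.188 to 2.64) lay within 1 kb of a gene end against 9.85% of other regions called in exactly 2 libraries. Weak peaks at the calling threshold stay open: within DMSO replicate 2 their median percentile by fold was 17.5 against 22.2 for regions shared only by DMSO replicates 1 and 2, a difference of −4.67 (permutation p = 0.0216), although the latter pair showed no such excess (ratio 0.922). Reads from another cell type cannot be told apart from this, because only 2 of 272 regions near a gene (0.735%, interval 0.0892 to 2.63) were nearest to a marker of the 6 other cell types (1 erythroid, 1 lymphoid), against 1.05% of other regions, and the interval spans that share. The sort for HSC surface markers would remove most such cells.

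The clustering of tunicamycin-only regions at 29 genes is a hypothesis of coordinated opening at single loci. The general tendency of any 3 libraries to call neighbouring regions together is argued against only weakly, since among the other 6 sets of 3 libraries with enough regions the smallest share of draws with as many genes was 0.092 and the numbers were 0.759 to 1.17 times the median of draws, against 1.61 times and an adjusted p of 0.042 over 7 sets for the tunicamycin set. With regions within 10 kb of each other counted as 1, there were 23 genes against a median of 15 in draws (9 to 23, 1.53 times, share 0.034), so the excess was little smaller and fragments of one broader region are neither shown nor excluded. With peaks of q at most 1e-05 there were 18 against 13 (7 to 20, 1.38 times, share 0.074) on 439 in place of 536 regions, and with lists of one length 10 against 7 (1.43 times, share 0.168), so peaks near the calling threshold stay open. A direct effect of tunicamycin on these loci therefore remains untested by these lists.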
